A study of Mus musculus with 3 samples.

How the data were processed

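Expression was measured with 1-colour Illumina MouseRef-8 v2 bead arrays in 3 samples of total RNA, 1 each of immature (imDC), semi-mature or tolerogenic (tDC) and fully mature (mDC) dendritic cells. Per the labels' protocols, 550 ng of RNA was amplified and labelled with biotin. Groups came from the cell type given in the labels, and each sample was the only one of its group. The deposited table of unprocessed arrays gave for each probe an average signal, a linear intensity, per the file headers, and a detection p-value, which was also deposited per the file headers. GenomeStudio 2011.1 is named in the submitters' processing notes. The authors' processed values were deposited as log2 intensities, as their comparison with the signals showed. Each of those columns had a median of 6.98 and held the same set of values in another order, as quantile normalization gives, and each ranked the probes as that array's signals did (Spearman correlation 1.00 across probes). Their shared distribution departed from the mean of the 3 arrays' sorted signals by at most 0.14 and at the median by 0.01 on the log2 scale, for a reason not given in the sources used here.

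The authors' signals were background corrected here with the normexp model, with parameters from the detection p-values and an offset of 16, then quantile normalized over the 3 arrays and expressed as log2 (neqc in limma 3.58.1, R 4.3.3). A probe was kept if its detection p was under 0.01 on at least 1 array, which left 11556 of 25697 probes. The platform annotation gave 1 gene symbol to 23978 probes and several to 0. The other 1719 probes are unnamed here, 688 of them among the kept ones, and entered no count. Symbols were checked through Entrez gene IDs against a RefSeq gene table of assembly GRCm38.p6, which held 23962 of the named probes. Where a gene had several kept probes, the one with the highest mean log2 level represented it, which gave 8055 genes. No named gene that differed by 2-fold had another detected probe with a difference of the opposite sign. Over all genes at 2-fold with a second detected probe, that probe had the same sign for 67 of 67 in tDC against imDC, 157 of 157 in mDC against imDC and 69 of 69 in mDC against tDC, and also reached 2-fold for 49, 122 and 58.

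Differences were taken between log2 values of pairs of arrays, first named minus second. With 1 array per group no test was made. A gene counted as higher or lower at a log2 difference of 1 or more. A gene detected on only 1 array of a pair was given as a bound ("at least"), set against the higher of the lowest detected value on the other array and the probe's own value there. A gene detected on neither had no fold. Every gene was also placed in a profile class by 2-fold steps over the 3 arrays. For 25 gene lists and 9 lists of cell type markers, fixed before the data were examined, the median log2 difference of the measured members was placed among 10000 random lists of the same size drawn from 20 bins of mean level, as a percentile that describes these arrays. Named genes followed a rule fixed at the same time. It took, per comparison, the 10 largest rises and 10 largest falls among genes detected on both arrays, the 3 largest bounds each way, up to 4 members of each list with a difference of at least 2-fold, and any member of the costimulatory, cytokine, MHC class II, T cell inhibitory and reference lists. Predicted or unnamed gene models were left out of the largest changes.

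The steps were tested on simulated arrays of 8263 genes, in the comparison of tDC with imDC. With 50 genes at each size, 100% of genes raised by 1.5 on the log2 scale and 96% of those lowered by 1.5 (a log2 change of -1.5) were called, as were 100% of genes raised by 3 and 100% of those lowered by the same amount (-3). Of 8063 unchanged genes, 7 were called. Of 60 unchanged lists, 1 lay outside the central 95% of random lists. Those lists were random draws from the unchanged simulated genes, so that count checks the procedure, not lists of genes regulated together. The changed genes were drawn from bright probes only, so recovery of dim genes was not measured. The simulated arrays had small random noise and no variation between cultures, so the 7 calls give no rate of false calls in the real data.

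Signals ran from 63.8 to 65567 intensity units, the top close to the limit of such scanners, so differences of the brightest genes can be understated. Probes of closely related genes (H2, Saa, Lyz, Oas and Bcl2a1 families) can bind transcripts of their relatives, and array probes for H2 genes can bind the alleles of this strain unequally, so those genes are uncertain. No time of harvest is given for imDC in the labels, and stimulus and hours of stimulation changed together, so no difference can be assigned to either. Alternatives set before the data were examined were no background correction, median scaling in place of quantile normalization, an offset of 50, the authors' processed values, a looser filter (detection p under 0.05), detection on all 3 arrays, no filter, and the mean of a gene's kept probes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the counts, lists and plots.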

Results

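Gene expression was measured in 3 preparations of dendritic cells grown from mouse bone marrow, with 1 Illumina bead array for each. Dendritic cells take up antigen and present it to T cells. Marrow of DBA mice aged 6 weeks was cultured for 8 days with GM-CSF at 20 ng/ml and interleukin-4 at 2 ng/ml, which drives marrow precursors toward dendritic cells. The imDC group was the immature culture, with no stimulus named in the labels. For the tDC group, which the labels call semi-mature or tolerogenic, TNF-alpha at 10 ng/ml and type II collagen at 50 µg/ml were added for 4 h. For the mDC group, called fully mature, lipopolysaccharide at 1 µg/ml and the same amount of collagen were added for 24 h. Of 25697 probes, 11006 were detected on the imDC array, 10764 on the tDC array and 10673 on the mDC array, at a detection p under 0.01. The median signal was 132 intensity units for imDC, 125 for tDC and 125 for mDC. There were 8055 named genes detected on at least 1 array. With 1 array per group there was no test, p-value or standard error for any difference, and the number of arrays limits the precision of every value. Genes were counted as higher or lower at 2-fold. The only measure of error was the scatter between probes of a gene, which leaves out the variation between cultures. In the comparison of tDC with imDC, the log2 differences of 2 detected probes of the same gene disagreed by a median of 0.13 over 1846 genes.

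The first comparison set cells given TNF-alpha and collagen for 4 h (tDC) against the immature culture (imDC). The tDC array had higher signals for 7 of 17 inflammatory cytokines, 11 of 21 genes of the NF-kB list and 8 of 16 cholesterol synthesis genes, and lower signals for 3 of 14 genes of lipid handling and sterol efflux and 2 of 25 cell cycle genes. The largest differences among genes detected on both arrays were those of Saa3, an acute-phase protein (25.8-fold higher), the chemokine Cxcl1 (22.7-fold), Clec4e, a receptor for mycobacterial glycolipids (21.1-fold), and Tnf (18.3-fold). Cxcl2, Chil1, Apol7c, Schip1, Ccrl2 and Il1b followed, from 12.1-fold for Cxcl2 to 6.99-fold for Il1b. Among the 10 largest falls were Abcg1, a sterol exporter (5.93-fold lower), Ccdc80 (4.85-fold), Galnt9 (4.52-fold), Eps8 (4.41-fold) and Fbp1, an enzyme of gluconeogenesis (4.26-fold). Daglb, Fcrls, Lipn, F13a1 and Zranb3 were 4.21-fold to 3.91-fold lower. Hspa1a, an inducible heat shock protein, was not above background in imDC and was at least 16.7-fold higher in tDC. Cxcl10 was at least 8.07-fold and Ednrb at least 6.55-fold higher in tDC on the same terms. Ccn4 was at least 4.54-fold, Chd5 at least 3.75-fold and C1qc at least 3.41-fold lower in tDC, where none of them was above background.

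In the tDC comparison, 227 genes were higher and 159 were lower than in imDC among 7884 genes detected on at least 1 of the 2 arrays. Of these, 205 and 149 were detected on both. Without background correction 148 genes were higher and 79 lower, and 14 of 85 named differences shrank by over 1.5 times, among them those of Saa3 (14.9-fold), Schip1 (4.44-fold), Galnt9 (2.68-fold), Hspa1a (at least 8.05-fold), Cxcl10 (at least 4.18-fold) and Il12a (at least 2.94-fold). With the mean of a gene's probes in place of the brightest, Daglb was 2.25-fold lower and Ednrb at least 2.84-fold higher. In all, 15 of the 85 differences, which leave out that of Il6 given below, went under 2-fold in at least 1 alternative. Without background correction these included Cd70 (1.89-fold), Idi1 (1.82-fold), Dusp2 (1.82-fold), Lad1 (1.81-fold), Cma1 (1.69-fold), C1qb (1.93-fold), Cxcl3 (at least 1.59-fold), Cd209a (at least 1.62-fold), Pfkp, Tfrc and Tk1, and in other settings H2-DMa (1.88-fold) and Pfkp (1.80-fold) with median scaling, and Adgre1 (1.82-fold) and Tk1 (1.52-fold) with the mean of probes.

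Of 17 measured inflammatory cytokines, 7 were higher in tDC than in imDC and 0 were lower. They included Il1a (6.27-fold), Il6 (3.70-fold) and Il12a, a subunit of interleukin-12, which was at least 5.32-fold higher. The median log2 difference of the list was 0.90, above all of 10000 random lists matched on level (percentile 100). With genes below background on 1 array set at their bound, and those below on both at 0, it was 0.81. Of 18 chemokines, 4 were higher and 0 lower (Cxcl1, Cxcl2, Cxcl10 and Cxcl3), and the list median of 0.27 turned to -0.06 when only genes detected on all 3 arrays were kept. With genes below background on 1 array at their bound it was 0.08, inside the range of random lists, which had no bounds set. NF-kB subunits, inhibitors and targets were higher for 11 of 21 genes, with a median of 1.02 (percentile 100). Their largest differences were those of Nfkbiz (6.80-fold), Tnfaip3, an inhibitor of NF-kB signalling (3.98-fold), Sod2 (3.24-fold) and Tnfaip2 (3.17-fold). Among pattern recognition genes, 5 of 21 were higher, including the lipopolysaccharide co-receptor Cd14 (4.32-fold), Irak3, a brake on Toll-like receptor signalling (3.94-fold), and Tlr2 (3.46-fold), while the list median was 0.02 (percentile 63.9). Signalling feedback inhibitors were higher for 4 of 18 genes, with a median of 0.26 (percentile 99.9), led by Irak3, Zc3h12a (2.49-fold) and Dusp4 (2.46-fold). Of 17 immediate early genes, Nr4a3 was 3.57-fold and Dusp2 2.37-fold higher and Klf4 2.61-fold lower, with a list median of 0.06. None of 29 interferon-stimulated genes differed by 2-fold, and their median was -0.05 (percentile 28.5).

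Cholesterol synthesis genes were higher in tDC for 8 of 16 members, with a median log2 difference of 1.00 (percentile 100). Hsd17b7 (3.92-fold), Msmo1 (3.07-fold), Idi1 (2.62-fold) and Cyp51 (2.43-fold) led this list of sterol synthesis enzymes. Among 14 genes of lipid handling and sterol efflux 3 were lower, Abcg1, Scd2 (3.67-fold) and Scd1 (2.41-fold), the latter pair being fatty acid desaturases. The median of that list was -0.31 (percentile 0.21). Cell cycle genes had a median of -0.60 (percentile 0), and 2 of 25 were lower at 2-fold, Ccnd1, which encodes cyclin D1 (3.45-fold), and Tk1 (2.23-fold). Glycolysis and hypoxia genes had a median of -0.32 (percentile 0.01), with Pdk1 (2.56-fold), Egln3 (2.09-fold) and Pfkp (2.01-fold) lower and Slc2a6 (3.03-fold) higher. The 13 genes of nitric oxide, arginine and oxidative burst had a median of 0.28 (percentile 99.6), and there Arg2 was 3.41-fold higher and Arg1 2.37-fold lower. Among 19 genes of endoplasmic reticulum and heat stress 1 was higher, Hspa1a, and the median was 0.00. Casp4 (2.63-fold) and Fas (2.32-fold) were higher among 15 apoptosis regulators, whose median of -0.10 became 0.03 under median scaling. Ctsk, a lysosomal protease, was 2.64-fold lower among 17 lysosome and autophagy genes, whose median was -0.13 (percentile 7.0). Genes of the TCA cycle and respiratory chain had a median of -0.19 (percentile 0.78), with 0 of 23 at 2-fold.

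Of 9 measured costimulatory ligands 2 were higher, Cd40 (2.64-fold) and Cd70 (2.48-fold), and 0 were lower. The log2 differences of Cd86 and Cd80 were 0.28 and -0.01, and the list median was 0.29 (percentile 98.9). Of 18 T cell inhibitory and tolerance genes 2 were higher, the interleukin-1 receptor antagonist Il1rn (3.14-fold) and Hmox1 (2.66-fold), with a list median of 0.06 (percentile 76.7). Cd274, which encodes PD-L1, differed by 0.75 and Ido1, which degrades tryptophan, by -0.28. Il10 was not above background on either array. None of 18 MHC class I presentation genes differed by 2-fold, with a median of 0.08. Of 16 MHC class II presentation genes H2-DMb1 (2.28-fold) and H2-DMa (2.05-fold), which load peptide on class II, were lower, and the median was -0.26 (percentile 0.43). Antigen uptake receptors went both ways, with 4 higher and 3 lower of 20 and 7 above 0. Their median was -0.42 (percentile 0), or -0.12 with genes below background on 1 array at their bound. The latter lay inside the range of random lists, which had no bounds set. Clec4e, Clec4d (4.55-fold) and Cd207 (at least 3.39-fold), the langerin of Langerhans cells, were higher, and Clec10a was 2.57-fold lower. The migration list of maturing dendritic cells had a median of 0.48 (percentile 99.99), with 1 of 11 at 2-fold, Lad1 (2.22-fold). In that list the homing receptor Ccr7, named here after its value was seen, differed by 0.47.

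Markers of other cell types also differed between tDC and imDC. Neutrophil and granulocyte precursor markers were higher for 8 of 15 genes, with a median of 1.04 (percentile 100), led by Chil1 (10.9-fold), Lcn2 (5.12-fold), Mmp9 (3.31-fold) and Csf3r (3.00-fold). Mast cell and basophil markers had a median of 0.82 over 8 genes (percentile 99.99), with Hdc, the enzyme of histamine synthesis, 5.94-fold and Cma1 2.28-fold higher. Macrophage and monocyte markers had a median of -0.45 over 13 genes (percentile 0), with C1qc (at least 3.41-fold) and C1qb (2.28-fold) lower and Ly6c1 (2.67-fold) and Adgre1 (2.15-fold) higher. Few markers of further types were detected. The medians were 0.73 for 5 T and NK cell genes (percentile 99.6), 0.57 for 4 erythroid and platelet genes (percentile 98.8) and 0.48 for 4 stromal genes (percentile 98.3). With genes below background on 1 array at their bound, and those below on both at 0, these became 0.27, 0.57 and 0.47. The 0.27 lay inside the range of random lists, which had no bounds set. The medians of 0.23 for 6 B and plasma cell genes and 0.17 for 6 plasmacytoid dendritic cell genes lay inside that range. Dendritic cell markers had a median of -0.04 over 11 genes, and Itgax, which encodes CD11c, was 2.29-fold and Cd209a at least 2.31-fold lower. Reference genes had a median of 0.01 over 7 genes, but Tfrc, the transferrin receptor, was 2.00-fold higher.

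The second comparison set cells given lipopolysaccharide and collagen for 24 h (mDC) against the immature culture. The mDC array had higher signals for 26 of 29 interferon-stimulated genes and 9 of 17 inflammatory cytokines, and lower signals for 8 of 16 MHC class II presentation genes and 13 of 25 cell cycle genes. Saa3 was 488-fold, Cxcl1 53.2-fold, Rsad2, an antiviral enzyme, 35.8-fold, Clec4e 34.5-fold and Hp, which encodes haptoglobin, 31.3-fold higher. Isg15, Ifit3, Schip1, Irf7 and Tnf were 27.1-fold to 24.4-fold higher. The largest falls were those of Fbp1 (63.2-fold), Fcrls (61.7-fold), the mannose receptor Mrc1 (47.2-fold), Ccnd1 (27.6-fold) and Zranb3 (25.2-fold). Hr, Eef1a2, Scd1, Mgl2 and Arg1 were 21.4-fold to 14.3-fold lower. Il12a was at least 94.1-fold, Lox at least 66.2-fold and Cyp1b1 at least 50.5-fold higher in mDC, each below background in imDC. Ccdc80 was at least 32.5-fold, Klk1b11 at least 32.0-fold and Aldh3a1 at least 14.5-fold lower.

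In the mDC comparison 491 genes were higher and 476 were lower than in imDC among 7973, of which 401 and 394 were detected on both arrays. Without background correction 28 of 117 named differences shrank by over 1.5 times, among them those of Saa3 (275-fold), Fbp1 (37.5-fold), Fcrls (35.9-fold), Il12a (at least 42.9-fold), Lox (at least 30.3-fold) and Cyp1b1 (at least 23.2-fold). With the mean of a gene's probes Hr was 9.62-fold and Klk1b11 at least 13-fold lower, Oasl1 was at least 14.4-fold higher, and Ccr6, at 1.86-fold lower, no longer reached 2-fold. In all, 15 of the 117 went under 2-fold in at least 1 alternative, among them Cd200r1 (at least 1.85-fold) and Cd209a (at least 1.59-fold) without background correction. Il1b, Csf2, H2-Ab1, Ciita, Havcr2, Cd274, Cd200 and Il1rn, given below at 2-fold or more for mDC against imDC, are not among the 117. The imDC array entered both comparisons with it. Of 227 genes higher in tDC, 157 were also higher in mDC, against 14.3 for independent lists of those sizes. Of 159 genes lower in tDC, 126 were also lower in mDC, against 9.70. A simulation of unchanged arrays against the shared one gave 0 in each direction, but it held the scatter between probes only and left out variation between cultures, so it is no baseline. Part of the excess may come from the shared array.

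Interferon-stimulated genes were higher in mDC than in imDC for 26 of 29 members, with a median log2 difference of 2.41 (percentile 100). Beside Rsad2, Isg15 and Ifit3, Oasl1 was at least 31.9-fold higher. Inflammatory cytokines were higher for 9 of 17, with a median of 1.85, or 1.03 with genes below background on 1 array at their bound. Il6 was 17.3-fold, Il1a 16.3-fold and Il1b 11.9-fold higher. Csf2, which encodes GM-CSF, was at least 4.00-fold higher. Chemokines were higher for 10 of 18 and lower for 2, with a median of 1.22 (percentile 100). Cxcl2 was 20.1-fold, Cxcl10 at least 19.2-fold and Cxcl3 at least 6.28-fold higher. NF-kB genes were higher for 14 of 21, with a median of 1.17 (percentile 100), led by Nfkbiz (7.55-fold) and Sod2 (5.16-fold). Pattern recognition genes were higher for 8 of 21 and lower for 1, with a median of 0.86 (percentile 100). Irak3 was 7.60-fold and Ddx58, the RIG-I sensor of viral RNA, 5.08-fold higher, and Tlr8 was at least 3.20-fold lower. Nos2, the inducible nitric oxide synthase, was at least 8.67-fold and Ptges, a prostaglandin synthase, at least 15.6-fold higher, while Arg1 was lower. Of the 13 genes in that list, 6 were higher and 1 was lower.

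Presentation genes went apart by class in mDC. MHC class I presentation genes had a median of 0.70 (percentile 100), with 4 of 18 higher, namely Nlrc5 (2.57-fold), H2-K1 (2.56-fold), Tapbpl (2.42-fold) and Tapbp (2.28-fold). MHC class II presentation genes had a median of -0.97 (percentile 0), with 8 of 16 lower and 0 higher. H2-DMa (4.54-fold), the protease Lgmn (4.50-fold), H2-DMb1 (3.57-fold), H2-Ab1 (2.06-fold) and Ciita, the transcription factor of class II genes (2.14-fold), were lower. The invariant chain Cd74 differed by -0.56 and Marchf1 by 0.92. Of 9 costimulatory ligands 3 were higher, Cd40 (6.89-fold), Cd70 (6.05-fold) and Slamf1 (2.78-fold), and Cd86 and Cd80 differed by 0.52 and 0.29. The list median was 0.52 (percentile 99.5), or 0.29 with genes below background on 1 array at their bound. The latter lay inside the range of random lists, which had no bounds set. Of 18 T cell inhibitory and tolerance genes 6 were higher and 2 lower. Il10 was at least 4.57-fold, Hmox1 3.93-fold, Ido1 2.69-fold, Il1rn 2.62-fold, Cd200 2.52-fold and Cd274 2.19-fold higher, and Cd200r1 (at least 2.78-fold) and Havcr2 (2.03-fold) were lower. Antigen uptake receptors had 5 genes higher and 7 lower of 20, with a median of -0.62 (percentile 0), or -0.34 with genes below background on 1 array at their bound. Mrc1, Mgl2 (16.1-fold) and Clec10a (at least 12.5-fold) were lower, whereas Clec4e was higher. In the migration list 2 of 11 genes were higher and 2 lower, with a median of 0.53. Among inflammatory chemokine receptors 3 were measured, of which Fpr2 was 5.58-fold higher and Cxcr2 (4.42-fold) and Ccr6 (3.08-fold) were lower.

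Cell cycle genes had a median of -1.04 in mDC against imDC (percentile 0), with 13 of 25 lower and 0 higher. Beside Ccnd1, the mitotic genes Birc5 (3.45-fold), Cdca8 (3.44-fold) and Cdc20 (3.28-fold) were lower. Genes of lipid handling and sterol efflux had a median of -0.87 (percentile 0), with 6 of 14 lower, including Scd1 (19.0-fold), and 1 higher, Apoc2 (4.61-fold). Cholesterol synthesis genes had a median of -0.26 (percentile 3.79), with 1 of 16 lower, Dhcr7 (3.60-fold). Cytosolic ribosomal protein genes had a median of -0.35 over 13 genes (percentile 1.84), with 0 at 2-fold, and the reference genes had -0.08, which became 0.09 under median scaling. Neutrophil markers had a median of 0.36 (percentile 99.8), with 6 higher and 2 lower of 15. Mast cell and basophil markers had 1.28 (percentile 100), with 5 of 8 higher, and Hdc was 21.7-fold higher. Few markers of other types were detected. The medians were 1.18 for 5 T and NK cell genes, 1.13 for 6 B and plasma cell genes, 2.28 for 4 erythroid and platelet genes, 2.08 for 4 stromal genes and 0.37 for 6 plasmacytoid dendritic cell genes. With genes below background on 1 array at their bound, and those below on both at 0, these became 0.32, 0.61, 1.98, 1.41 and 0.37. The values for T and NK cells and for B and plasma cells then lay inside the range of random lists, which had no bounds set. The plasmacytoid dendritic cell value lay inside that range with and without bounds. Macrophage markers had a median of -0.51 (percentile 0.10), with 2 higher and 6 lower of 13. Adgre1 was 7.99-fold and Ly6c1 7.62-fold higher, and C1qb was at least 6.74-fold and Retnla 6.54-fold lower. Dendritic cell markers had a median of 0.05 (percentile 64.9), with Itgax 3.88-fold and Cd209a at least 2.24-fold lower and Irf8 2.18-fold higher.

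The third comparison set mDC against tDC, 2 states that differed in stimulus and in hours of stimulation together. Interferon-stimulated genes were higher in mDC, cholesterol synthesis genes were lower, and NF-kB genes did not differ by 2-fold. Ifit3 was 45.6-fold, Cyp1b1 29.0-fold, Vnn3 25.5-fold, Irf7 23.9-fold and Rsad2 23.4-fold higher in mDC, and Cmpk2, Isg15, Saa3, Il12a and Ifit2 followed at 22.8-fold to 16.1-fold. Lox was at least 60.9-fold, Oasl1 at least 29.4-fold and Cfb, a complement factor, at least 21.2-fold higher. Mrc1 was 23.8-fold, Fcrls 14.9-fold, Fbp1 14.8-fold, Hr 10.5-fold and Eef1a2 9.66-fold lower, and Mgl2, Ccnd1, Scd1, Rab15 and Hspa1a were 8.66-fold to 6.73-fold lower. Asprv1 was at least 15.9-fold, Klk1b11 at least 11.8-fold and Aldh3a1 at least 9.13-fold lower. In all, 269 genes were higher and 219 lower in mDC than in tDC among 7831, and without background correction 188 and 132. In that setting 25 of 88 named differences shrank by over 1.5 times, among them those of Cyp1b1 (17.4-fold), Vnn3 (14.9-fold), Fcrls (8.98-fold), Lox (at least 29.2-fold) and Asprv1 (at least 8.11-fold). With the mean of a gene's probes Hr was 4.53-fold and Klk1b11 at least 4.71-fold lower, and Oasl1 was at least 19.0-fold higher. In all, 13 of the 88 went under 2-fold in at least 1 alternative, among them Havcr2 (1.98-fold) without background correction and H2-Ab1 (1.98-fold) with median scaling. Csf1, given below at 2-fold or more, is not among the 88.

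Between the stimulated states, 26 of 29 interferon-stimulated genes were higher in mDC and the median was 2.53 (percentile 100). The NF-kB list had 0 of 21 genes at 2-fold and a median of 0.05 (percentile 84.5). Of 16 cholesterol synthesis genes, 12 were lower in mDC, with a median of -1.31 (percentile 0), led by Cyp51 (3.76-fold), Fdps (3.69-fold), Sqle (3.29-fold) and Msmo1 (2.87-fold). Inflammatory cytokines were higher for 5 of 17 and lower for 1, with Il6 at 4.66-fold higher, Csf2 at least 3.68-fold higher and Csf1 2.52-fold lower. Among costimulatory ligands Cd40 (2.62-fold), Cd70 (2.44-fold) and Slamf1 (2.08-fold) were higher. Among T cell inhibitory and tolerance genes Il10 (at least 4.21-fold), Ido1 (3.27-fold) and Lgals9 (2.97-fold) were higher and Havcr2 was 2.13-fold lower, and the list median ran from -0.023 to 0.022 over the normalizations tried. Glycolysis and hypoxia genes had a median of 0.41 (percentile 100), with 0 of 21 at 2-fold. MHC class II genes had a median of -0.63 (percentile 0), with Lgmn (2.53-fold), H2-DMa (2.21-fold) and H2-Ab1 (2.10-fold) lower. In this comparison the neutrophil markers had a median of -0.25 (percentile 1.60) and the mast cell and basophil markers 0.49 (percentile 99.97). The 4 erythroid and platelet genes had 1.53 and the 4 stromal genes 1.13, or 0.88 with genes below background on 1 array at their bound. On the same terms the macrophage median of -0.51 became -0.22 and that of 6 B and plasma cell genes went from 0.80 to 0.49. Both lay inside the range of random lists, which had no bounds set.

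**Figure D1:**
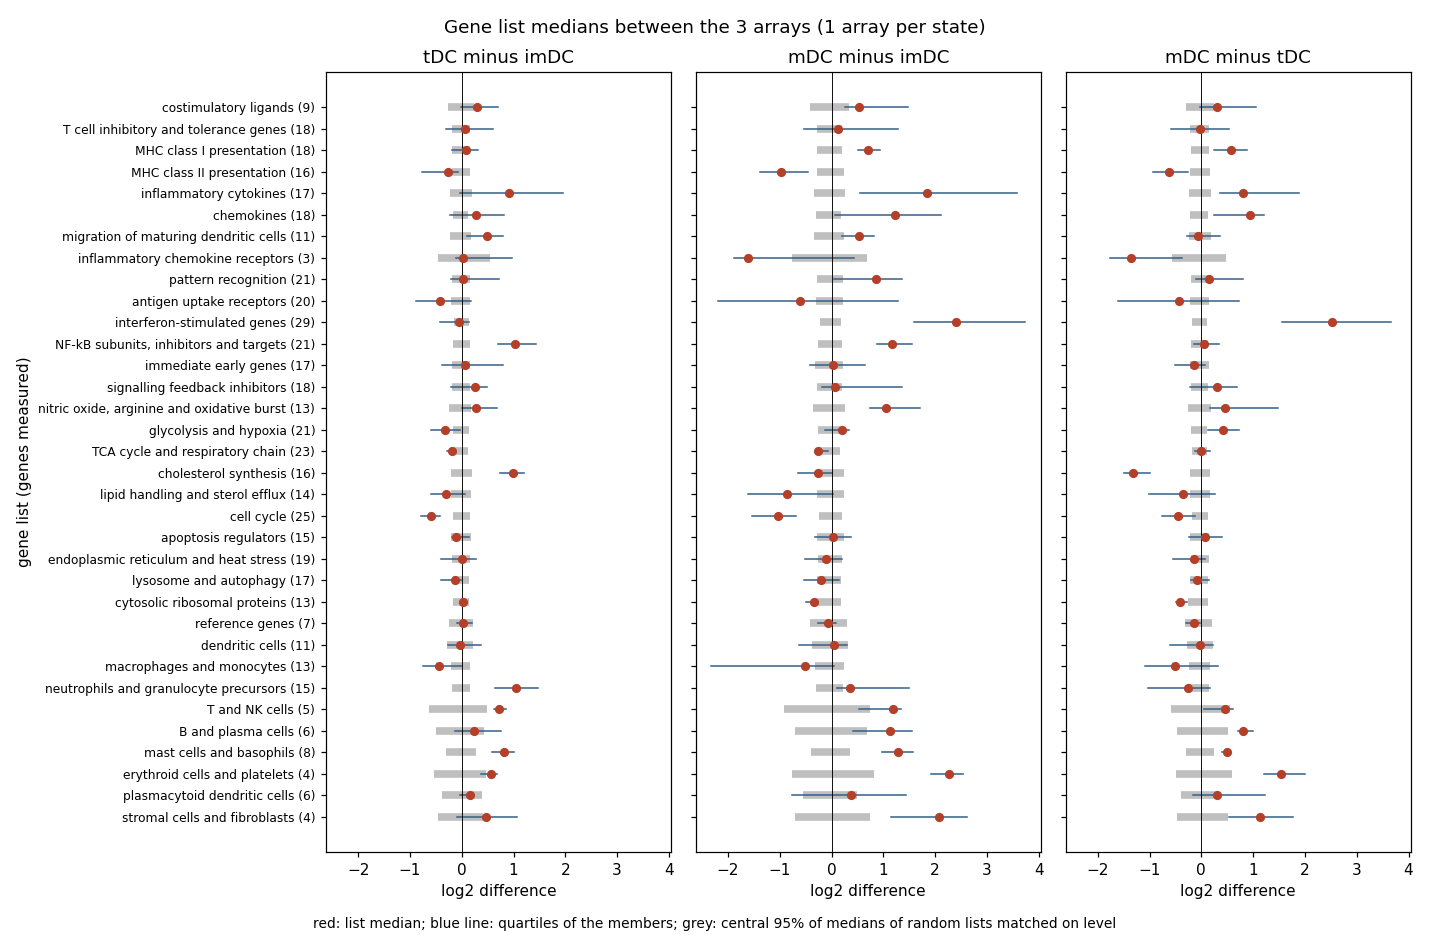
Median log2 difference of each gene list between pairs of arrays (red points; x axis, log2 difference; y axis, list with the number of genes measured), with the quartiles of the members as blue lines and the central 95% of medians of matched random lists as grey bars. Interferon-stimulated genes lie at 2.41 in mDC against imDC and at -0.05 in tDC against imDC, while cholesterol synthesis genes lie at 1.00 in tDC against imDC.

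Profiles over the 3 arrays were sorted into classes by 2-fold steps. There were 233 genes highest in mDC, of which 24 were interferon-stimulated genes of the 29 measured, and 161 lowest in mDC, or 97 without background correction. A further 112 genes were higher in both stimulated states than in imDC and within 2-fold between them, 11 of them from the NF-kB list. Lower in both were 92 genes, or 45 without background correction. The tDC array had the highest value for 29 genes (18 without background correction), and 7 of the 29 were cholesterol synthesis genes (Cyp51, Fdps, Hmgcs1, Hsd17b7, Insig1, Msmo1 and Sqle, of which Hmgcs1 and Insig1 were chosen after their values were seen). It had the lowest value for 4 genes, Abi3, Cnn3, Csprs and Mgarp, named after their values were seen, a count that fell to 0 without background correction.

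**Figure D2:**
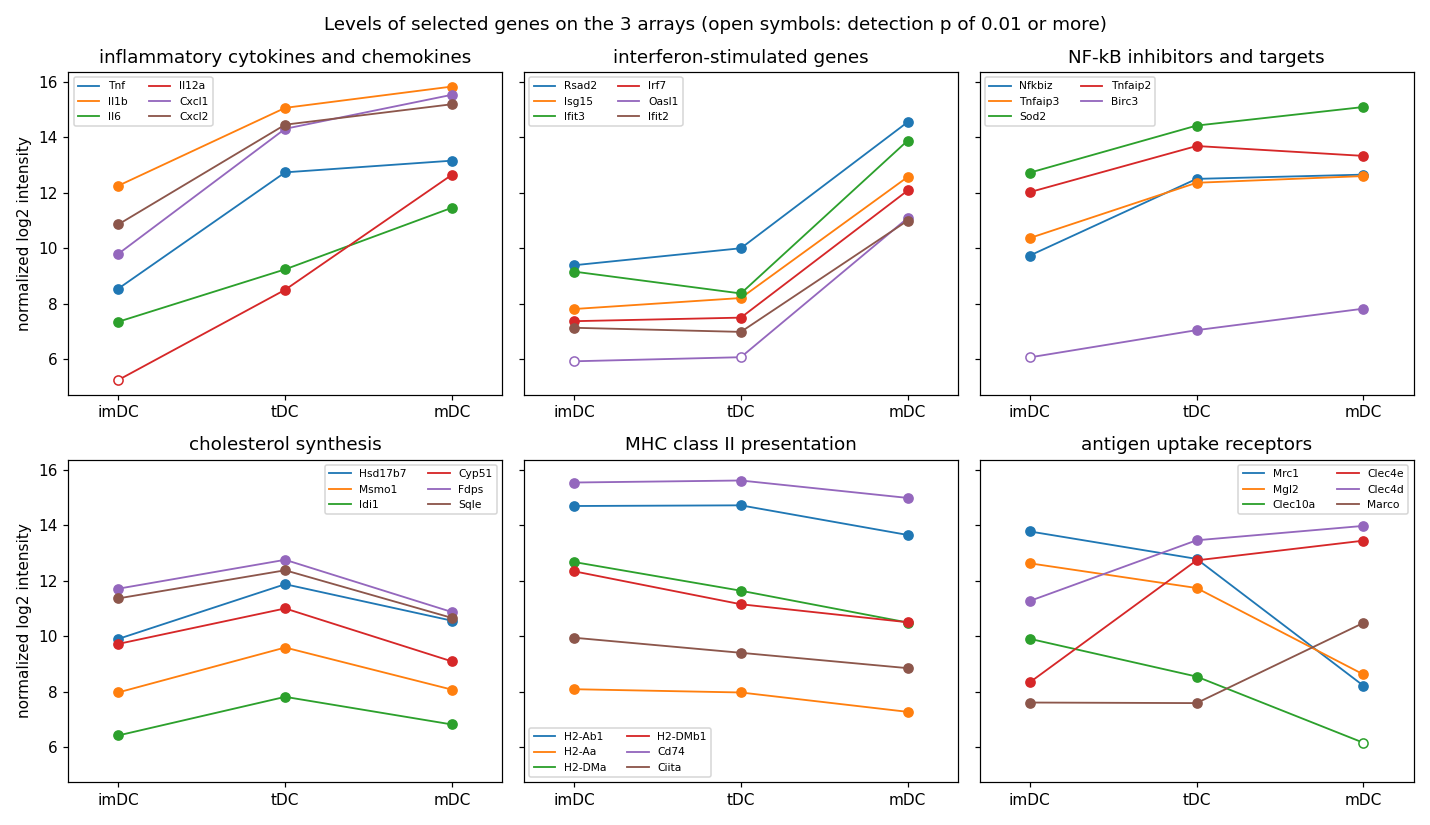
Normalized log2 intensity (y axis) of selected genes on the imDC, tDC and mDC arrays (x axis), 1 array each, with open symbols where the probe was not above background. Tnf differed from imDC by 4.19 in tDC and 4.61 in mDC, Rsad2 by 0.61 and 5.16, Cyp51 by 1.28 and -0.63, and Mrc1 by -0.99 and -5.56.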

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

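All alternatives here were set before the data were examined. No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. Median scaling, detection on all 3 arrays and the mean of a gene's probes left all 12 counts (6 of genes at 2-fold and 6 of profile classes) within 1.5 times. The genes counted as higher in tDC than in imDC went from 227 to 148 without background correction. Those lower in tDC went from 159 to 79 without background correction and 85 with the authors' processed values, those lower in mDC than in tDC from 219 to 132 and 136, those highest in tDC from 29 to 18 and 19, those lowest in mDC from 161 to 97 and 100, and those lower in both stimulated states from 92 to 45 and 47. Genes lowest in tDC, 4 in number, became 0 without background correction, 0 with the authors' processed values, 2 with an offset of 50, and 7 both with detection p under 0.05 and with no filter on detection. Signals that keep their background give smaller differences by construction, most of all for dim genes. Without background correction 148 of the 227 higher and 79 of the 159 lower genes of tDC against imDC were called again in the same direction, and 369 of 491 and 339 of 476 in mDC against imDC.

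Over 102 list medians and 8 alternatives, 21 values had the other sign than the main value, in 14 lists and comparisons. For 18 of them the main median lay inside the range of random lists, so no direction is read from it, and for 3 it lay outside. Apart from those 3, 792 values lay within 1.5-fold of the main value and 21 further off. The chemokine median in tDC against imDC became -0.061 with detection on all 3 arrays, which drops the chemokines below background on an array. The median of the inflammatory chemokine receptors in mDC against imDC, -1.62 over 3 genes, became 0.24 with detection p under 0.05 and 0.057 with no filter, which add dim genes to the list. The 290 differences named as largest changes, bounds or leading list members were followed through the alternatives. Of their values 2078 lay within 1.5-fold of the main value, 176 further off and 0 had the other sign. Without background correction 67 of 290 were smaller by over 1.5 times, by at most 2.20 times, and with the authors' processed values 67, by at most 2.12 times. With the mean of a gene's probes 11 were smaller, by at most 2.51 times, such as those of Daglb in tDC against imDC (4.21-fold to 2.25-fold) and of Hr (21.4-fold to 9.62-fold) and Klk1b11 (at least 32.0-fold to at least 13-fold) in mDC against imDC. With no filter 20 were larger, by at most 3.08 times, and with detection p under 0.05 there were 11, by at most 1.54 times. Bounds given as "at least" hold for the main setting only, since they move in the same way. The median log2 difference of all genes moved from its main value by at most 0.068, in mDC against imDC. Signal over background set the limit for dim genes, which have bounds in place of folds.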

Other observations

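In these observations the test of neutrophil content and the test of dendritic cell content were chosen after values they use had been seen, and the medians of the fixed lists were known when the others were written.

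Arg1 and Arg2, and some macrophage markers, differed from imDC in opposite directions within their own lists. Arg1, an enzyme tied to interleukin-4 signalling, had normalized log2 differences from imDC of -1.25 in tDC and -3.84 in mDC, while the mitochondrial form Arg2 had 1.77 and 1.63. Among macrophage and monocyte markers, Adgre1 differed from imDC by 1.10 and 3.00 and Ly6c1 by 1.42 and 2.93, whereas Retnla, also tied to interleukin-4, differed by -0.76 and -2.71 and the receptor Mertk by -0.45 and -2.32. Retnla and Mertk did not reach 2-fold in tDC. Hdc rose across the states, with 2.57 in tDC and 4.44 in mDC. Among plasmacytoid dendritic cell markers Bst2, also an interferon-stimulated gene, was 3.87-fold higher in mDC than in imDC and Cox6a2 at least 6.66-fold lower. Of 688 kept probes with no name here, 17 were higher and 20 lower in tDC than in imDC, and 37 were higher and 52 lower in mDC.

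Neutrophil markers were higher in tDC than in imDC, with a list median of 1.04, and all 15 measured members were detected in imDC as well. The choice among the background corrections and normalizations tried is argued against as the whole cause. The median was at least 0.94 under the 4 others, where it would have had to fall under 0.5. All of them set the arrays to a like median or distribution, so an error they share was not tested. More neutrophils or precursors in the tDC culture stays open and cannot be told apart from induction in the cultured cells. The 10 granule and lineage genes had a median of 0.94, with 9 of them at 0.5 or more. This is below the 1.73 of 5 members set apart as also induced by inflammatory stimuli, but not low enough to exclude the explanation. That split is uncertain, since 4 of the 5 reached 0.5 in tDC and 1 of the 5 was below 0 in mDC against imDC. Cxcr2, a neutrophil marker of the list, differed by 0.03 in tDC. S100a8 and S100a9, abundant in neutrophils, differed by 0.69 and 0.56. No sort of the cultures is named in the labels.

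Cholesterol synthesis genes were higher in tDC than in imDC and lower in mDC than in tDC. The choice among the background corrections and normalizations tried is argued against as the whole cause of the rise, since the list median was at least 0.90 under the 4 others. All of them set the arrays to a like median or distribution, so a shared error was not tested. A low-sterol state, with targets of the liver X receptors lower, may accompany the rise, but 5 targets whose values had not been seen had a median of -0.14 (percentile 24.9 of matched random lists), which decides nothing. Abcg1, another target, had been seen to differ by -2.57 and was not in that test. Hours of stimulation and the stimulus cannot be told apart, because the median of -1.31 in mDC against tDC spans both.

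MHC class II genes were lower in mDC than in imDC. The choice among the normalizations tried is argued against as the whole cause by a list median of -0.83 or lower under the 4 others. An error shared by all of these settings was not tested. A lower share of dendritic cells was not decided. The 11 dendritic cell markers outside class II had a median of 0.052. It lay above the class II median of -0.97 by more than their interquartile range of 0.93, though by a small margin. The markers differed both ways, with Itgax at -1.96 and Irf8 at 1.13, so their median is no sure measure of that share. Lower Ciita transcription stays open. Ciita itself differed by -1.10, but the 8 genes known to depend on its protein had a median of -1.07, a difference of -0.26 from the 7 other pathway genes. That gap became -0.24 with H2-Ob, below background in mDC, at its bound (median -1.05), -0.21 without Marchf1 and -0.20 with both changes. These are under the 0.25 set in advance as too small for this explanation, but by less than the interquartile range of the 8 genes (1.11, or 0.53 with the bound). A first run had missed Marchf1 under its older symbol, and the symbol was corrected, and the comparison with the interquartile range added, after the gap of -0.21 had been seen. Biological regulation by the stimulus was not tested apart from the hours of culture.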
